A study of Mus musculus with 45 samples.

How the data were processed

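Forelimbs of gestation day 13 mouse embryos were pooled and cultured in bottles with DMSO or with 10 or 50 µM BPS, per the labels' protocols, with limbs of both sexes in one culture. RNA was taken after 3, 24 or 48 h. Poly-A RNA was fragmented and copied into cDNA from random hexamers, NEBNext adaptors were ligated and the libraries were amplified by PCR, per the labels' protocols. The kit is not stated to keep strand, so reads of overlapping and antisense genes could not be separated, and values of such genes are uncertain. The design text names CD1 mice only. The strain labels of the 5 libraries of 50 µM at 48 h read CD2 to CD6, 1 library each, and these libraries were analysed as CD1. Groups and replicate numbers came from the sample titles. The labels do not say whether libraries of one group came from separate cultures or litters, so p-values measure the spread between these libraries, which may in part be technical. The Y-linked gene Ddx3y stood at 0 CPM in control 3 h replicate 1 and at 65.0 CPM in replicate 2. This argues against copies of one RNA pool for these libraries. Whether they shared a culture or litter stays open.

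The submitters' processing notes name CASAVA 1.8, STAR 2.5, HTSeq 0.6.1, DESeq2 (listed with version 2) and the mouse genome build mm10, with no role or order for each. The annotation release and the options of each step are not given in the sources used here. The deposited data were 9 tables, 1 per comparison made by the authors, each with 10 libraries. Per the file headers each table holds raw read counts per gene and library, which the authors did not normalise, and these counts were the input of every test here. Log2 fold changes and p-values with their adjusted values were computed by the authors and deposited in the same tables, per the file headers. They were used here only to count genes at an adjusted p below 0.05. Of the adjusted p-values deposited by the authors 0 were missing. The FPKM values and the scaled counts were not used here. Gene symbols, identifiers, coordinates and lengths are those of the deposited tables.

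The tables were joined by gene identifier into 34994 genes with 34969 unique symbols. Control libraries occur in more than 1 table, and of 1319925 control counts found more than once 0 differed. The smallest total of a gene in a table was 2 reads, and a gene listed in one table but missing from another had at most 1 read in any library common to both, so missing genes were set to 0. All 9 tables held 0 columns of other samples. Totals ran from 15.2 to 23.1 M reads per library. A count of 3 reads, the floor used for a level of 0, lies between 0.13 and 0.197 CPM in single libraries. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 4.63 over genes. The reads carry no molecular identifiers, so floors cover counting error only.

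The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, the filterByExpr filter and robust dispersion. Each comparison of 2 groups was fitted on its own 10 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p below 0.05 counted as a call. The SE of a log2 fold change was taken from its size and the F statistic of that test. The difference of the 50 µM response between times was tested as an interaction in a fit of the 45 libraries on 18432 genes. CPM values used TMM factors over the 45 libraries, and log2 CPM for the components and list scores a prior count of 2. In all, 35 gene lists covering skeletal differentiation, limb signalling, lipid and stress pathways, other cell types and RNA quality were fixed. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with the correlation estimated from the libraries, for lists with at least 5 genes tested, and adjusted over the lists of a comparison.

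Named genes followed a rule. Among genes with an adjusted p below 0.05, at least 1 CPM on average and a symbol other than a gene model name, the 10 largest rises and the 10 largest falls of each comparison were taken, with up to 4 members of each list by smallest adjusted p. A panel of 15 skeletal, hedgehog, estrogen receptor and cholesterol genes was set to be named in each case. Some genes that these rules name, and 1 from the interaction test, are not reported here, but all counts and list tests include them. Where fewer than 10 genes passed, the 5 with the smallest p were named as not passing. Gm13111 and genes given for their interaction or their spread alone were named after their values were seen. Groups, lists, main tests, the naming rule and the other fits were fixed before the data were examined. The covariate given next, the test of a lower share of non-skeletal cells, the hypoxia tests by replicate number and the score of the 48 h genes at 24 h were chosen after the result was seen. The other tests of explanations were set once a pattern was seen, before their own result was.

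The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, the fit of all 45 libraries, a limit of 1 on the absolute log2 fold change, and each library left out in turn. The summed CPM of 4 Y-linked genes as a covariate was added after the sex-linked levels had been seen. Correlations of the doses were also computed with split controls and for genes of at least 10 CPM. Replicate numbers are shared between groups, and the labels do not say that a number marks a litter, bottle or day. Same-numbered libraries of control and 50 µM at 3 h deviated together in all 5 pairs (correlation over genes 0.114 to 0.243), with 8 of 10 libraries closest to their own number, so the blocked values stand beside that comparison.

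The tests were tested on simulated data, drawn for the genes and library sizes of single comparisons with 200 changed genes, 50 per fold size. For 50 µM at 48 h (16450 genes) edgeR recovered 72% of genes changed 1.5-fold, 84% at 2-fold and 98% at 3-fold, and called 5 unchanged genes. For 50 µM at 24 h (16305 genes) it recovered 68%, 88% and 100%, with 9 unchanged genes called, and for 50 µM at 3 h (16499 genes) 76%, 98% and 98%, with 16. The interaction test between 48 and 3 h (18124 genes) recovered 54%, 72% and 100%, with 4 unchanged genes called. A list of 25 genes planted at 1.3-fold was called in each of 4 simulated comparisons with either correlation, and a list without planted changes was not. The simulated genes were drawn independently of each other. The simulation therefore cannot show how either list test behaves for lists whose genes vary together.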

Results

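Forelimb buds of CD1 mouse embryos, taken on gestation day 13, were kept as organ cultures in medium with vehicle (DMSO, called control here) or with bisphenol S (BPS) at 10 or 50 µM. Their poly-A RNA was sequenced after 3, 24 or 48 h. BPS is a bisphenol used in place of bisphenol A. The limb bud at this age holds a cartilage model that ossifies later through endochondral ossification, the process named in the series title. There were 9 groups of 5 libraries, 45 libraries in all. Each library held between 15.2 and 23.1 M reads assigned to genes, with a median of 18.2 M. Expression levels are given as counts-per-million (CPM) with the SD over n = 5 libraries, and fold changes as log2 values with their standard error (SE). On the first principal component, which took 46.9% of the variance of the 2000 most variable genes, the 3 culture times lay apart without overlap, while the doses of one time overlapped. The second component took 8.22%.

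**Figure D1:**
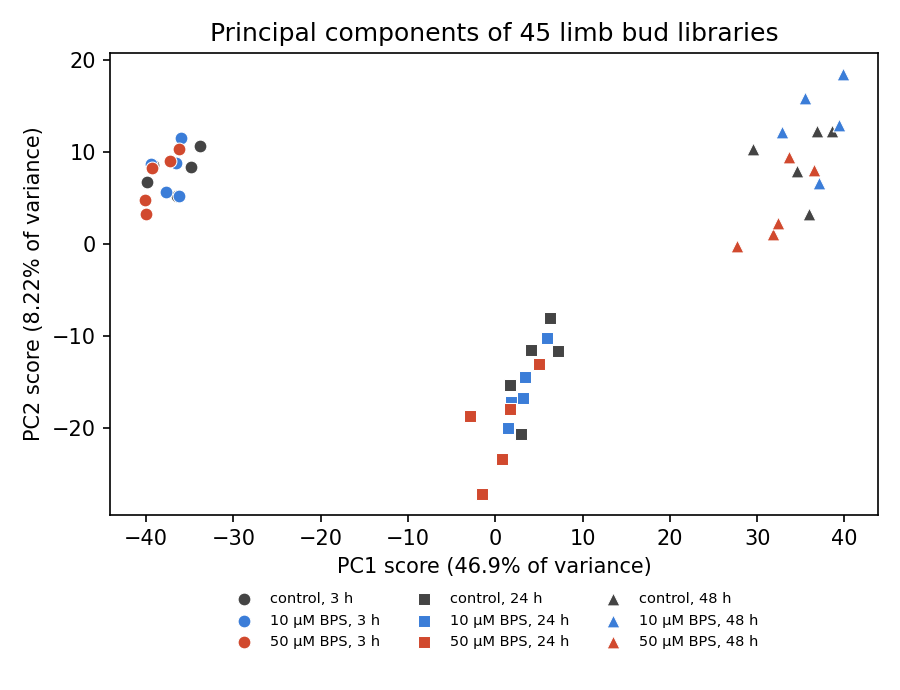
Scores of the 45 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; marker shape gives the time in culture and colour the dose. The 3 times separate along the first component, with 46.9% of the variance.

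The first question was what culture alone did to the limb bud over time, since every BPS comparison stands on that background. Between 3 and 24 h of control culture, 25 of the 26 tested genes of cartilage matrix and early chondrocytes rose, by a median of 1.302 on the log2 scale. Col2a1, the main fibrillar collagen of cartilage (ENSMUSG00000022483, mm10 chromosome 15, 97975602 to 98004695, minus strand), went from 2598 ± 163 to 6335 ± 196 CPM, a log2 change of 1.29 ± 0.053 (adjusted p = 2.81e-13). Acan, which encodes the proteoglycan aggrecan, rose from 154 ± 18.0 to 405 ± 9.7 CPM. Sox9, the transcription factor of chondrocyte identity, stood at 462 ± 24.9 and 479 ± 14.4 CPM and did not pass (adjusted p = 0.412). Col10a1, the collagen of hypertrophic chondrocytes, rose from 4.73 ± 0.978 to 24.3 ± 11.7 CPM. In the hypertrophic list 12 of 15 genes rose. Among osteoblast and bone matrix genes 12 of 17 rose and 1 fell. Ibsp, a mineral-binding bone sialoprotein, stood at 75.1 ± 22.7 CPM after 0.810 ± 0.618 (log2 change 6.48 ± 0.435, adjusted p = 4.44e-06). Sp7, the osteoblast transcription factor, rose by 1.05 ± 0.096 and Runx2 by 0.65 ± 0.059 on the log2 scale.

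Over the same interval 28 of 29 cell cycle genes fell, with a median of -0.97, among them Ccnb1 from 115.5 ± 6.98 to 49.7 ± 2.64 CPM. Limb patterning genes fell in 21 and rose in 5 of 36 cases, including the homeobox gene Msx2 at -1.73 ± 0.103. Hedgehog target genes rose in 10 of 11 cases and 1 fell, with Ptch1, the hedgehog receptor, at 0.84 ± 0.060. The ligand gene Ihh went from 22.9 ± 2.47 to 47.3 ± 8.71 CPM. Skeletal muscle genes rose in 23 of 25 cases. Genes of cells other than the skeletal lineage moved both ways: 9 of 14 erythroid genes fell (median -1.23), 15 of 17 endothelial genes fell (median -0.53), and 12 of 17 macrophage and leukocyte genes rose while 1 fell (median 0.92). Plvap and Aplnr, both markers of vessel endothelium, fell by 2.54 ± 0.132 and by 2.53 ± 0.085. Lyz2, a myeloid lysozyme, rose from 2.75 ± 0.512 to 28.1 ± 4.93 CPM.

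Adjusted over the list alone, the counts that rose in this interval were 25 for cartilage, 14 for hypertrophic genes, 12 for osteoblast genes, 10 for hedgehog targets, 23 for muscle and 12 for macrophage genes. Counted the same way, 28 cell cycle, 22 limb patterning, 10 erythroid and 15 endothelial genes fell, while 5 limb patterning genes rose and 1 gene each of the osteoblast, hedgehog and macrophage lists fell. The camera list test called 11 lists higher and 8 lower of the 35. With an estimated correlation 6 higher and 5 lower lists were called. These included cartilage (adjusted p = 0.000155), hypertrophic genes (0.00798), osteoblast genes, hedgehog targets and limb patterning (each 0.0143), cell cycle (0.0117), muscle (0.0339) and erythroid genes (0.025). The endothelial call (adjusted p = 2.06e-08) was lost, at adjusted p = 0.0833 with an estimated correlation. The macrophage call (adjusted p = 3.73e-10) was lost too, at adjusted p = 0.0590 with an estimated correlation. Over all 16536 genes tested, edgeR called 6642, 3315 higher and 3327 lower, of which 950 changed at least 2-fold. The authors' deposited table held 6665 genes at an adjusted p below 0.05, and 6341 were called in both.

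From 24 to 48 h, 12 of 18 osteoblast and bone matrix genes rose (13 adjusted over the list alone, median 0.77). Col1a1 went from 2702 ± 204 to 6782 ± 590 CPM and Alpl, the phosphatase of mineralising cells, from 27.6 ± 3.72 to 66.3 ± 8.69 CPM. Col10a1 rose from 24.3 ± 11.7 to 160.0 ± 81.8 CPM, a log2 change of 2.71 ± 0.487 (adjusted p = 0.00634). In the hypertrophic list 8 of 16 genes rose (9 adjusted over the list alone). Of the p53 target and apoptosis genes 15 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), such as Cdkn1a, a cell cycle inhibitor, at 1.09 ± 0.077. Limb patterning genes fell in 22 of 35 cases (24 adjusted over the list alone), for example Hoxd13 at -0.57 ± 0.067. Stra6, a retinol transporter, fell from 24.4 ± 3.26 to 10.0 ± 1.41 CPM. Sox9 fell by 0.25 ± 0.061 on the log2 scale. These 4 lists were called with an estimated correlation too, each with an adjusted p of 0.0168 or 0.0164.

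On the second day Krt1, a keratin of differentiating epidermis, went from 21.2 ± 8.18 to 211 ± 41.7 CPM and Krt77 from 0.688 ± 0.466 to 18.6 ± 8.59 CPM. On the list as a whole 6 of 20 epidermal genes rose (7 adjusted over the list alone; adjusted p = 3e-11, and adjusted p = 0.159 with an estimated correlation). Cartilage genes rose in 19 of 27 cases and 1 fell (19 and 2 adjusted over the list alone; adjusted p = 2.89e-17, and adjusted p = 0.133 with an estimated correlation), with Acan at 0.89 ± 0.087. Macrophage genes rose in 14 of 18 cases (18 adjusted over the list alone; adjusted p = 2.11e-12, and adjusted p = 0.0693 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 26 cases (16 adjusted over the list alone; adjusted p = 2.97e-05, and adjusted p = 0.201 with an estimated correlation), with Idi1 at -0.44. The count for this day was 2670 of 16694 genes, 1576 higher and 1094 lower, with 393 at 2-fold or more. The authors' deposited table held 3036, and 2660 were called in both.

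Across the whole span from 3 to 48 h, 8304 of 16850 genes changed, 4126 higher and 4178 lower, and 1854 of them by at least 2-fold. The authors' deposited table held 8574, with 7949 in both. Ibsp reached 442 ± 117 CPM, a log2 change of 9.04 ± 0.4. Slc4a1, the band 3 protein of red cells, fell from 21.2 ± 3.48 to 1.27 ± 0.263 CPM. Cartilage genes rose in 26 of 27 cases with 1 lower (26 and 1 adjusted over the list alone, median 1.96). Hypertrophic genes rose in 16 of 16 cases (16 adjusted over the list alone, median 1.66) and macrophage genes in 16 of 17 (16 adjusted over the list alone, median 1.496). These 3 lists were called with the preset and with an estimated correlation (adjusted p = 0.0180, 0.00992 and 0.00992 with an estimated correlation). Some epidermal genes had 0 reads in the 5 control libraries at 3 h, so their fold is a lower bound against a floor of 3 reads over the group. Krt6b, at 4.77 ± 2.68 CPM at 48 h, was at least 140-fold higher, and Dsc1, a desmosomal cadherin, at least 70.1-fold higher. Krt6b has a near-identical neighbour, Krt6a, with which reads can be shared. The same holds for Stfa3 and BC100530 (5.87 and 5.33 higher on the log2 scale at 48 h) among the stefin genes, so these values are uncertain.

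The comparison of 10 µM BPS with control asked whether the lower dose changed expression at any of the 3 times. At 3 h the cartilage list lay slightly below control (median -0.06, 0 of 26 genes passing and 0 adjusted over the list alone). The erythroid list also lay lower (median -0.15, 0 of 14 and 0 adjusted over the list alone) and the endoplasmic reticulum (ER) chaperone list higher (median 0.05, 0 of 17). The camera test called these 3 lists (adjusted p = 0.00281, 1.15e-05 and 0.00281), and none held (adjusted p = 0.843, 0.521 and 0.299 with an estimated correlation). The cartilage call was lost without 10 µM replicate 3 (adjusted p = 0.266) or control replicate 3 (0.19) or 2 (0.0517), and its median was -0.04 without 10 µM replicate 5 or control replicate 4 and -0.10 without control replicate 1. The erythroid median was -0.10 and -0.23 without 10 µM replicates 1 and 2. At 24 h no list was called. Left-out libraries moved these counts, to 6 lists at 3 h without 10 µM replicate 1, 4 or 5 or without control replicate 5, to 5 without control replicate 4, and to 7 at 24 h without control replicate 5. At 24 h the count was also 4 without control replicate 3 or 10 µM replicate 5, 3 without 10 µM replicate 1 or 2, 2 without control replicate 1 and 1 without control replicate 2 or 4.

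At 48 h of 10 µM BPS the epidermal list had a median of 0.33 with 0 of 21 genes passing (0 adjusted over the list alone; adjusted p = 1.49e-12, and adjusted p = 0.544 with an estimated correlation). The median was 0.18 without 10 µM replicate 2. Klk7, a protease of the outer epidermis, stood at 2.95 ± 0.62 CPM against 1.37 ± 0.49, a log2 difference of 1.11 ± 0.253 (adjusted p = 1). Cyp1a1, a target of the aryl hydrocarbon receptor, stood at 5.55 ± 0.863 against 3.49 ± 0.583 CPM, with an adjusted p of 1. Cpm, a membrane carboxypeptidase, stood at 85.3 ± 9.37 against 69.2 ± 3.45 CPM with an adjusted p of 1. Muscle genes had a median of -0.11 with 0 passing (adjusted p = 0.000137, and adjusted p = 0.616 with an estimated correlation). This call was lost without 10 µM replicate 4 (median -0.06, adjusted p = 0.066) or control replicate 5 (adjusted p = 0.0551), and the median was -0.16, -0.21 and -0.07 without 10 µM replicate 5 and control replicates 3 and 1. The cholesterol synthesis list had a median of 0.06 with 0 of 26 passing (adjusted p = 0.00612, and adjusted p = 0.544 with an estimated correlation). It was not called without 10 µM replicate 2 (median 0.02, adjusted p = 0.0518) or control replicate 5 (adjusted p = 0.127), and the median was 0.03 without replicate 4 of either group. In all 6 lists were called higher and 2 lower at 48 h, and 0 with an estimated correlation. The count of lists was 12 without 10 µM replicate 5, 5 without 10 µM replicate 4 and 2 without control replicate 5.

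No single gene passed at 10 µM. By edgeR 0 of 16654 genes were called at 3 h, 0 of 16529 at 24 h and 0 of 16725 at 48 h. In the same order 329, 494 and 438 had an unadjusted p below 0.05, fewer than the 833, 826 and 836 that chance alone gives. DESeq2 and limma-voom called 0 at each time, and the authors' deposited tables held 0. By edgeR without the filter on low counts 1 gene was called at 3 h. The smallest p at 3 h was that of Acyp2, with a log2 difference of 1.04 ± 0.267 (adjusted p = 1). At 24 h it was that of Brd3os, with a difference of -0.36 ± 0.086 (adjusted p = 0.999). On counts simulated from the 48 h libraries of this comparison, with 16500 genes, 70% of genes changed by 1.5-fold were recovered and 92% of those changed 2-fold. Smaller changes at 10 µM were often below what this test recovers. The simulated libraries were drawn independently, without structure shared between libraries, and only 48 h was simulated for this dose. Recovery on the real libraries may therefore be lower.

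At 50 µM BPS, 3 h of exposure raised genes of ER protein folding. Hspa5, the main ER chaperone (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand), stood at 609.6 ± 35.6 CPM against 509.7 ± 8.65 in controls, a log2 change of 0.26 ± 0.046 (adjusted p = 0.025). Xbp1, a transcription factor of the unfolded protein response (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893, plus strand), stood at 104 ± 4.05 against 83.3 ± 5.8 CPM, a change of 0.32 ± 0.053 (adjusted p = 0.025). These were 2 of the 17 tested genes of the ER chaperone list, and 11 rose adjusted over the list alone, with a median of 0.16 (adjusted p = 2.05e-15, and adjusted p = 0.0057 with an estimated correlation). With the replicate number as a block as well as an estimated correlation the list was not called (adjusted p = 0.0842), while 9 of its genes passed over all genes with the block. Gdf5, a growth factor of the developing joint, rose from 99.8 ± 7.17 to 124 ± 7.43 CPM, and Ypel1 from 33.7 ± 1.96 to 43.0 ± 1.91 CPM. Lower were Mettl17, a mitochondrial ribosome assembly factor (ENSMUSG00000004561, chromosome 14, 51884842 to 51893039, plus strand), at 21.5 ± 2.89 against 31.4 ± 3.12 CPM. Also lower were the zinc finger gene Zscan26 at -0.43 ± 0.056, the arrestin-domain gene Arrdc4 at -0.31 ± 0.054 and the splicing factor gene Rbm25 at -0.29 ± 0.052.

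Other lists moved at 3 h without a member passing over all genes. The cholesterol synthesis list had a median of 0.15, and 7 of its 26 genes rose adjusted over the list alone (adjusted p = 1.57e-10, and adjusted p = 0.04999 with an estimated correlation). For BMP and TGF-beta targets 3 of 14 genes rose adjusted over the list alone (median 0.13, and 0.08 without 50 µM replicate 2; adjusted p = 1.92e-06, and adjusted p = 0.0277 with an estimated correlation). For the retinoid pathway it was 4 of 15 (median 0.08, adjusted p = 0.000481, and adjusted p = 0.0309 with an estimated correlation). Erythroid genes lay lower, 3 of 14 adjusted over the list alone (median -0.24, adjusted p = 1.35e-07, and adjusted p = 0.0195 with an estimated correlation). With the replicate number as a block and an estimated correlation none of these 4 lists was called (adjusted p = 0.178 for BMP and TGF-beta targets and 0.0842 for each of the others), while with the block 7 cholesterol, 4 BMP, 4 retinoid and 2 erythroid genes passed over all genes. The cartilage list was called lower with a median of -0.06, 0 of its genes passing (adjusted p = 0.0033, and adjusted p = 0.705 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.0822) or 50 µM replicate 3 (0.139), and the median was -0.11 without control replicate 1. The immediate early list was called lower with a median of -0.15 (adjusted p = 7.75e-06, and adjusted p = 0.177 with an estimated correlation). Just above the threshold lay Manf, a secreted ER stress factor (0.34 ± 0.065, adjusted p = 0.0531), and Id1 and Id3, both BMP targets (0.31 and 0.27, adjusted p = 0.0531). So did Srsf2 (-0.26, adjusted p = 0.0531) and Txndc11 (0.25, adjusted p = 0.0563). With the replicate number as a block all 5 passed (adjusted p = 0.00455 for Manf, 0.000117 for Id1, 8.67e-05 for Id3, 0.00011 for Srsf2 and 0.00327 for Txndc11).

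Over all 16722 genes, 9 changed at 50 µM and 3 h, 5 higher and 4 lower. Over all genes tested, the 5 libraries of one group lay apart from the 5 of the other for 279 (1.67%), which chance gives for 1 gene in 126. The ninth gene was the gene model Gm13111 (0.36 ± 0.061). The authors' deposited table held 41 genes, which included all 9. Same-numbered control and 50 µM libraries deviated together at this time. With the replicate number as a block 256 genes passed, 134 higher and 122 lower, among them all 9. The count moved to 16 without control replicate 3, 18 without 50 µM replicate 2, 6 without 50 µM replicate 3 and 4 without control replicate 1 or 50 µM replicate 5. It fell to 2 without control replicate 4 and to 1 without control replicate 2 or 5 or 50 µM replicate 1 or 4. Zscan26 passed whichever library was left out, and the other named genes lost the call without 6 to 8 of the 10. Other settings gave 60 (no filter on low counts), 59 (DESeq2), 16 (limma-voom and the fit of 45 libraries), 23 (Y-linked level as a covariate, chosen after the levels were seen) and 0 at 2-fold or more.

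After 24 h at 50 µM, genes of cholesterol and fatty acid synthesis were higher than in controls. Among the 26 cholesterol genes 6 rose, with log2 changes of 0.35 ± 0.057 for Lss and 0.38 ± 0.063 for Dhcr7, both enzymes late in the pathway, and 19 adjusted over the list alone (median 0.21, adjusted p = 1.03e-22, and adjusted p = 0.0833 with an estimated correlation). Scd1, a fatty acid desaturase (ENSMUSG00000037071, chromosome 19, 44394451 to 44407709, minus strand), rose from 87.1 ± 11.9 to 133 ± 12.6 CPM, a change of 0.61 ± 0.087 (adjusted p = 0.0142). It was 1 of 3 rising genes of the 18 in the fatty acid list, with Scd2 and Fasn, while Plin2, a lipid droplet coat protein, fell by 0.30 ± 0.059. Adjusted over the list alone 7 rose and 4 fell (adjusted p = 0.0098, and adjusted p = 0.5 with an estimated correlation). Scd1 and Scd2 are close relatives, and reads could be split between them.

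The carboxypeptidase gene Cpm (ENSMUSG00000020183, chromosome 10, 117629500 to 117687352, plus strand) rose from 64.0 ± 3.6 to 85.4 ± 1.87 CPM (0.42 ± 0.052, adjusted p = 0.00119). The leptin receptor gene Lepr rose by 0.44 ± 0.070, the tight junction gene Cldn11 by 0.53 ± 0.096 and the lymphatic development gene Ccbe1 by 0.58 ± 0.101. The homeobox gene Dbx1, at a low level, rose from 1.297 ± 0.32 to 2.93 ± 0.714 CPM. Mettl17 was again lower, at 25.3 ± 1.11 against 38.5 ± 1.16 CPM, a change of -0.60 ± 0.062 (adjusted p = 0.00017). Osr2, a transcription factor of the joint region, fell by 0.35 ± 0.060 and Klf2, a factor of endothelial cells, by 0.43 ± 0.086. Among macrophage and leukocyte genes C1qb, a complement subunit, fell from 19.2 ± 3.03 to 13.3 ± 1.39 CPM, and Stab1, a scavenger receptor of macrophages and sinusoidal endothelium, fell by 0.46 ± 0.091. On the list, 1 of 17 fell and 6 adjusted over the list alone (median -0.26, adjusted p = 2.07e-08, and adjusted p = 0.432 with an estimated correlation). Stfa3 had the largest fall, from 2.88 ± 0.58 to 0.787 ± 0.462 CPM, with the uncertainty of the stefin genes given above.

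Of the skeletal genes, Osr2 aside, these were not called after 24 h: Sox9 differed by 0.10 (adjusted p = 0.421), Col2a1 by -0.03 (0.874), Acan by 0.02 (0.945), Ihh by 0.19 (0.599), Runx2 by 0.12 (0.355) and Col10a1 by -0.48 ± 0.466 (0.737). Skil, a target of TGF-beta signalling, rose by 0.34 ± 0.068. It was the 1 of 14 BMP and TGF-beta targets to pass (2 adjusted over the list alone; adjusted p = 0.00433, and adjusted p = 0.562 with an estimated correlation), and the list was not called without control replicate 5 (adjusted p = 0.0787) or 50 µM replicate 4 (0.0752). The hypoxia and glycolysis list was called lower with a median of -0.40 and 0 of 29 passing, Aldoa counting for 2 gene IDs (adjusted p = 3.19e-08, and adjusted p = 0.583 with an estimated correlation). Its median was -0.19 without control replicate 1, and its library scores spread by up to 1.38 log2 units within one group. The endothelial list, also lower, had a median of -0.14 and 0 of 17 passing (adjusted p = 0.00027, and adjusted p = 0.583 with an estimated correlation). Mitochondrially encoded genes lay higher, with 0 of 12 passing (median 0.27, adjusted p = 0.00264, and adjusted p = 0.583 with an estimated correlation). This call was lost without 50 µM replicate 1 (median 0.12, adjusted p = 0.102) and with the Y-linked level as a covariate, a fit added after the levels were seen (0.11, adjusted p = 0.123). The median was 0.18 without control replicate 3. They took 1.84% ± 0.311 of the reads against 1.63% ± 0.256 in controls. In all 5 lists were called higher and 7 lower, and 0 with an estimated correlation.

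Over all 16512 genes 62 changed at 24 h, 41 higher and 21 lower, 3 of them by at least 2-fold. The authors' deposited table held 268, 160 higher and 108 lower, with 61 in both. The count rested on single libraries, with 315 without control replicate 5 and 105 without 50 µM replicate 1. It was 21, 13, 15 and 7 without control replicates 3, 4, 1 and 2, and 3, 2 and 18 without 50 µM replicates 3, 4 and 2. Cpm and Mettl17 passed whichever library was left out, and the other named genes lost the call without 2 to 9 of the 10. Without the filter on low counts 153 genes were higher and 90 lower. Other settings gave 266 (DESeq2), 430 (limma-voom) and 104 in the fit of 45 libraries, which called 48 higher and 56 lower. With the replicate number as a block 949 passed, but not every same-numbered pair correlated above 0.1 at this time. The pairs ran from 0.079 to 0.246, and 9 of 10 libraries were closest to their own number. The count of 62 thus leaves out a possible pairing.

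After 48 h at 50 µM the cholesterol genes stood out further. Of 26 tested, 20 rose and 22 adjusted over the list alone, with a median of 0.44 (adjusted p = 6.34e-49, and adjusted p = 0.0260 with an estimated correlation). With the Y-linked level as a covariate, added after the levels were seen, the median was 0.67. Lss rose from 49.0 ± 2.05 to 78.7 ± 13.0 CPM, a log2 change of 0.68 ± 0.093, and Idi1 and Hmgcs1 rose by 0.79 and 0.59. Of the fatty acid list 6 of 18 rose, and adjusted over the list alone 10 rose and 3 fell (median 0.19, adjusted p = 7.5e-08, and adjusted p = 0.0260 with an estimated correlation). Scd1 had the largest rise of the genes called at 48 h, from 77.6 ± 5.42 to 147 ± 19.3 CPM (0.92 ± 0.081, adjusted p = 3.58e-05). Scd2, Acaca and Fads2 rose by 0.47, 0.29 and 0.28. Sex-linked genes lay higher in the same libraries, with 0 of 5 passing but 4 adjusted over the list alone (median 0.79, adjusted p = 3.61e-06, and adjusted p = 0.0610 with an estimated correlation). The summed level of 4 Y-linked genes was 205.9 ± 41.5 CPM at 50 µM and 117 ± 36.3 in controls.

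Markers of macrophages lay lower than in controls at 48 h. Csf1r, the receptor that macrophages need to survive (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149, plus strand), went from 25.9 ± 1.09 to 16.3 ± 2.97 CPM, a log2 change of -0.67 ± 0.104 (adjusted p = 0.00501). Lyz2 stood at 38.5 ± 9.27 against 60.6 ± 8.38 CPM, and C1qa and C1qc at -0.58 ± 0.131 and -0.58 ± 0.111. Fcrls, a microglia and macrophage gene, fell from 4.02 ± 0.829 to 1.57 ± 0.476 CPM and Msr1, a scavenger receptor, by 0.98 ± 0.206. On the list 4 of 18 fell and 14 adjusted over the list alone (median -0.40, adjusted p = 1.77e-16, and adjusted p = 0.0589 with an estimated correlation). Interferon response genes lay lower, with Oasl2 the 1 of 12 that fell and 5 adjusted over the list alone (median -0.45, adjusted p = 7.55e-06, and adjusted p = 0.0908 with an estimated correlation). Endothelial genes did likewise, with Cdh5 the 1 of 17 that fell and 4 adjusted over the list alone (median -0.19, adjusted p = 4.35e-05, and adjusted p = 0.318 with an estimated correlation). Mmrn1, a gene of lymphatic endothelium, fell from 2.85 ± 0.362 to 1.37 ± 0.189 CPM. The endothelial median was -0.28 and -0.12 without control replicates 5 and 1. With the Y-linked level as a covariate the medians were -0.65 for macrophage, -0.78 for interferon and 0.04 for endothelial genes, and the endothelial call was lost (adjusted p = 0.609). Muscle genes had a median of -0.03 with 0 of 26 passing (adjusted p = 0.251). The erythroid list was called lower too (median -0.28). Its call was lost without control replicate 3 (adjusted p = 0.112) or 1 (0.072) or 50 µM replicate 5 (0.0944). With the Y-linked level as a covariate its median was 0.06 (adjusted p = 0.599).

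**Figure D2:**
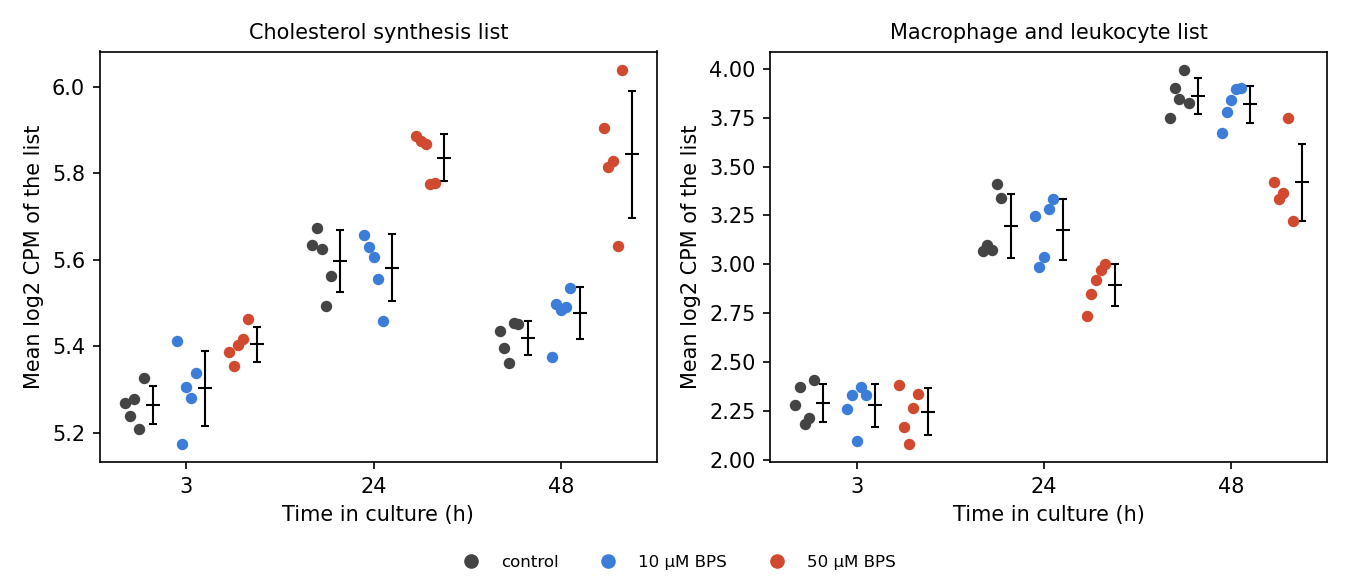
Mean log2 CPM of the cholesterol synthesis list (left) and the macrophage and leukocyte list (right) in each library against the time in culture in hours, coloured by dose; bars give the mean and SD of 5 libraries. At 48 h the 50 µM libraries differ from controls by 0.425 on the first list and -0.443 on the second.

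Among skeletal genes at 48 h, Ihh, the hedgehog ligand of prehypertrophic chondrocytes (ENSMUSG00000006538, chromosome 1, 74945315 to 74951672, minus strand), rose from 41.7 ± 9.2 to 64.4 ± 4.62 CPM, a log2 change of 0.63 ± 0.123 (adjusted p = 0.0295). It was the 1 of 16 hypertrophic genes to pass, 1 also adjusted over the list alone (median 0.08, adjusted p = 0.0402, and adjusted p = 0.336 with an estimated correlation). The list call was lost without control replicate 3 (adjusted p = 0.0555) or 5 (0.351) or 50 µM replicate 5 (0.144) or 1 (0.0732), and the median was 0.17 with the Y-linked level as a covariate. Gdf10, a BMP-family ligand, rose from 126 ± 11.6 to 198 ± 7.84 CPM. The BMP and TGF-beta target list lay higher with 0 of 14 passing and 7 adjusted over the list alone (median 0.17, adjusted p = 3.88e-05, and adjusted p = 0.0299 with an estimated correlation). Ucma, a cartilage matrix protein, fell from 5.12 ± 1.6 to 2.05 ± 0.353 CPM, the 1 of 27 cartilage genes to pass (2 lower adjusted over the list alone). The list was not called (median 0.03, adjusted p = 0.967). Thbs4, a matrix protein of tendon, and Osr2 fell by 0.59 ± 0.099 and 0.52 ± 0.072, 2 of the 19 joint and tendon genes (3 higher and 5 lower adjusted over the list alone). Aldh1a3, an enzyme that makes retinoic acid, fell from 24.6 ± 1.78 to 15.8 ± 1.39 CPM. None of Sox9 (0.12, adjusted p = 0.43), Col2a1 (0.03, 0.932), Acan (0.04, 0.909), Col10a1 (-0.45 ± 0.397, 0.699) or Mmp13 (-0.28, 0.814) passed. Neither did Runx2 (0.09, adjusted p = 0.662), Sp7 (0.00, 0.996), Gli1 (0.07, 0.684), Ptch1 (0.27, 0.3) or the estrogen receptor gene Esr1 (-0.11, 0.906). Of 18 osteoblast genes 0 passed (adjusted p = 0.982), and Shh and Fgf8 were too low to be tested.

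Cyp1a1 stood at 5.99 ± 1.24 against 3.49 ± 0.583 CPM, the 1 of 12 aryl hydrocarbon receptor genes to rise (adjusted p = 0.0399 for the gene and 0.91 for the list). Cpm rose to 107 ± 6.0 from 69.2 ± 3.45 CPM (0.63 ± 0.056, adjusted p = 3.58e-05), and Cth, an enzyme of cysteine synthesis, by 0.79 ± 0.138. The acetylcholinesterase gene Ache fell from 17.45 ± 2.08 to 8.76 ± 1.42 CPM, and the low-level genes Nptx2, Arhgdig and Ppp2r2c by 1.07, 1.02 and 0.97. Of the integrated stress response list 0 of 24 passed and 3 rose adjusted over the list alone (median 0.18, adjusted p = 4.85e-06, and adjusted p = 0.336 with an estimated correlation). Of the ER chaperone list 1 of 17 rose, Dnajb9, and 2 adjusted over the list alone (adjusted p = 0.00123, and adjusted p = 0.318 with an estimated correlation). Among mitochondrially encoded genes mt-Co1 rose from 4756 ± 425 to 6742 ± 378 CPM, the 1 of 12 to pass (median 0.18, adjusted p = 6.21e-05, and adjusted p = 0.318 with an estimated correlation). The median was 0.09 without control replicate 3 and 0.12 without 50 µM replicate 5. With the Y-linked level as a covariate the medians were 0.37 for the stress response and 0.02 for mitochondrially encoded genes, whose call was lost (adjusted p = 0.843), as was that of the ER chaperone list (adjusted p = 0.0546). Mitochondrial reads took 1.79% ± 0.085 of each library against 1.46% ± 0.136.

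**Figure D3:**
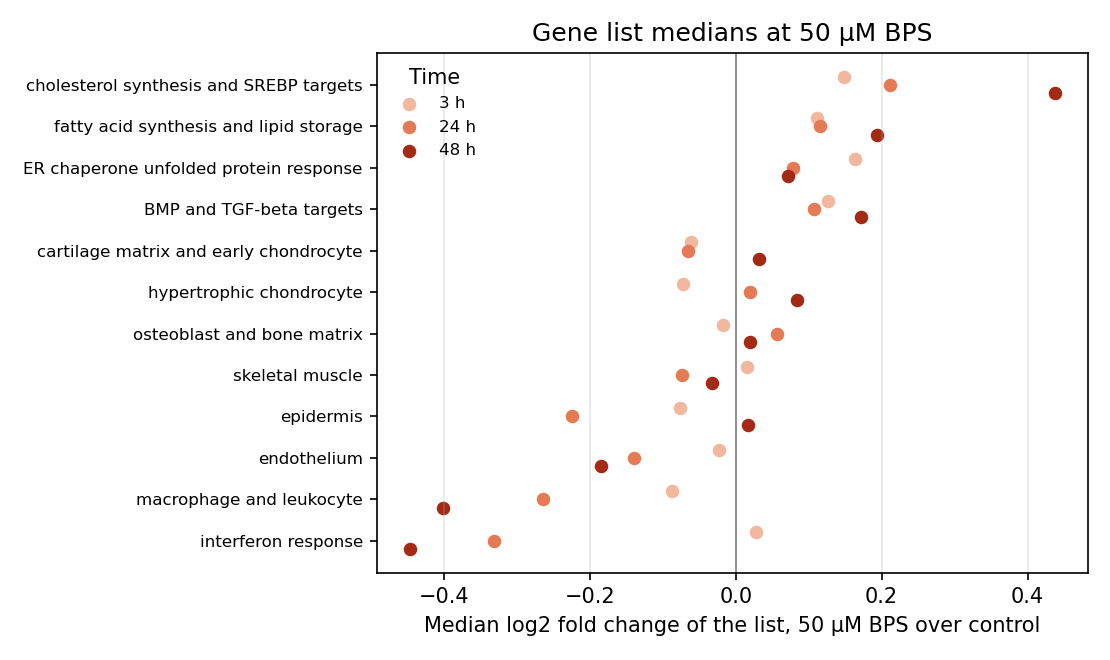
Median log2 fold change of 50 µM BPS over control (horizontal axis) for 12 gene lists at 3, 24 and 48 h, n = 5 libraries per group; each point is one list at one time. The cholesterol list lies at 0.149, 0.211 and 0.438, and the macrophage list at -0.264 and -0.401 at 24 and 48 h.

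Over all 16663 genes 167 changed at 48 h, 80 higher and 87 lower, and 7 were lower by at least 2-fold. Over all genes tested, the libraries of the groups did not overlap for 600 (3.60%), which chance gives for 1 gene in 126. The authors' deposited table held 435, 197 higher and 238 lower, with 166 in both. In all 9 lists were called higher and 9 lower, and with an estimated correlation 3, those of cholesterol, fatty acid and BMP genes. With the replicate number as a block as well, none of the 3 was called (adjusted p = 0.0728, 0.0728 and 0.124). The numbers were not taken to pair the libraries at 48 h. The count of genes was 282 without control replicate 1, 75 without control replicate 2 or 4, and 65, 66, 55 and 70 without 50 µM replicates 2, 3, 4 and 1. Scd1, Cpm, Lss, Idi1, Gdf10, Csf1r and Aldh1a3 kept an adjusted p below 0.05 whichever library was left out and in each other setting tried. Ihh lost the call without 6 of the 10 libraries, C1qa without 7, Cyp1a1, Lyz2 and Cdh5 without 8 and Oasl2 without 9. Other settings gave 258 (no filter on low counts), 426 (DESeq2), 516 (limma-voom), 477 (the fit of 45 libraries) and 35 with the Y-linked level as a covariate, a setting chosen after the levels were seen. With the replicate number as a block 70 genes passed.

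**Figure D4:**
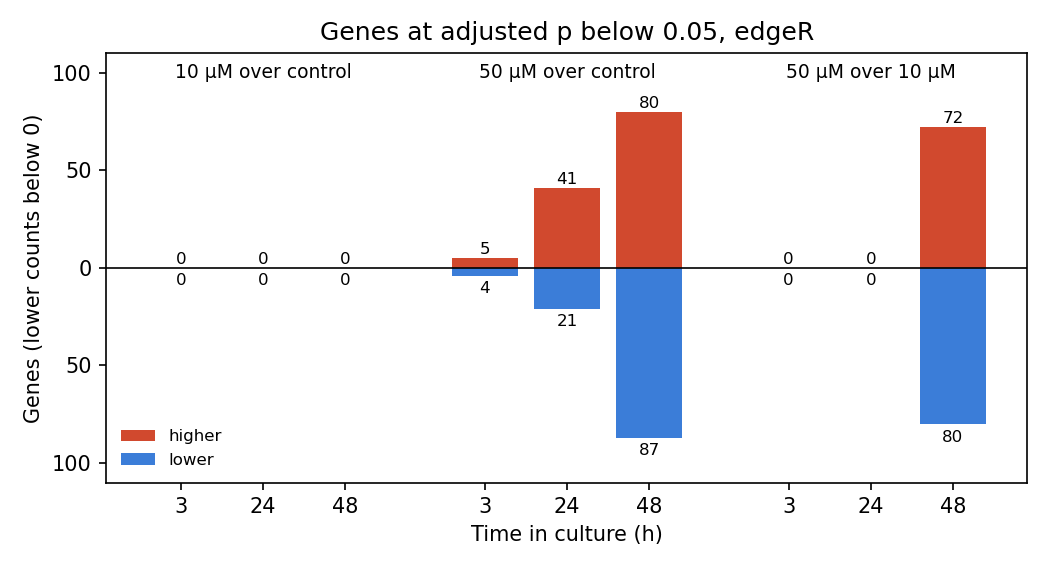
Genes at an adjusted p below 0.05 (edgeR) in each dose comparison at 3, 24 and 48 h, n = 5 libraries per group; bars above 0 count higher genes and bars below 0 lower genes. The 10 µM comparisons hold 0, and those of 50 µM over control 9, 62 and 167 genes in all.

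The doses were also compared directly. At 48 h the largest falls from 10 to 50 µM included some late epidermal genes, while the scores of the epidermis list overlapped (4.07 to 4.63 log2 CPM at 50 µM and 4.07 to 5.03 at 10 µM) and the list was not tested between the doses. Krt6b stood at 1.38 ± 0.648 against 8.97 ± 3.42 CPM, a log2 difference of -2.70 ± 0.341 (adjusted p = 0.0036). Klk7 stood at 0.804 ± 0.373 against 2.95 ± 0.62 CPM (-1.85 ± 0.280, adjusted p = 0.0021), and Spink5, Csta1 and Sprr1a, all genes of the cornified layer, at -2.04, -1.79 and -1.54. Controls at 48 h lay between the doses, with Krt6b at 4.77 ± 2.68 and Klk7 at 1.37 ± 0.49 CPM. For Krt6b and Klk7 the mean at 10 µM was above that of controls and the mean at 50 µM below it. No gene passed for 10 µM over control at 48 h, so a rise at 10 µM is not shown. Both genes were named for their gap between the doses. Higher at 50 µM was Scd1 at 147 ± 19.3 against 89.8 ± 4.48 CPM (0.71 ± 0.072, adjusted p = 0.000244). So were Insig1 (0.52 ± 0.068), Ihh (0.49 ± 0.101, adjusted p = 0.0408) and mt-Co1 (0.40 ± 0.045). Csf1r was lower, at 16.3 ± 2.97 against 25.9 ± 1.49 CPM (-0.66 ± 0.097, adjusted p = 0.00202). C1qa (-0.52 ± 0.098), Thbs4 (-0.56 ± 0.077) and Aldh1a3 (-0.48 ± 0.082) were lower as well. In all 152 of 16505 genes differed, 72 higher and 80 lower at 50 µM, and of the 19 that differed 2-fold or more 18 were lower. Other settings gave 469 (no filter on low counts), 352 (DESeq2) and 248 (limma-voom). The count was 88 without 10 µM replicate 1 and 97 and 93 without 50 µM replicates 3 and 4. Ihh, Spink5 and Sprr1a lost the call without 7, 5 and 6 of the 10 libraries.

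At the earlier times the doses were not told apart by the main test, with 0 genes at 3 h and 0 at 24 h by edgeR. At 3 h 737 genes had an unadjusted p below 0.05 where chance gives 835, and DESeq2 called 7, limma-voom 4, edgeR without the filter on low counts 13 and the fit of 45 libraries 1. Gdf5 (0.31, adjusted p = 0.0539) and Egr1 (-0.37, adjusted p = 0.0539) came closest. At 24 h 923 had an unadjusted p below 0.05 where chance gives 829, and DESeq2 called 37, limma-voom 26, edgeR without the filter 41 or with DESeq2 size factors 2, and the fit of 45 libraries 10. With the replicate number as a block, not taken to pair the libraries here, 181 genes passed at 24 h. The pairs correlated at 0.084 to 0.243, with 10 of 10 libraries closest to their own number, so the main test may miss paired differences. In the main test at 24 h Cpm (0.32) and Hmgcs1 (0.37) had an adjusted p of 0.0511 and Dhcr7 (0.37) and Scd1 (0.54) one of 0.055. Single libraries decided the calls of the main test. At 3 h 2 genes passed without 10 µM replicate 3 or 50 µM replicate 3 and 1 without 10 µM or 50 µM replicate 2. At 24 h it was 12, 10 and 2 without 10 µM replicates 3, 5 and 2, and 5 and 2 without 50 µM replicates 5 and 2. The effects of both doses share their control libraries. Across genes, which are not independent replicates, the log2 changes at 10 and at 50 µM correlated at r = 0.509, 0.554 and 0.48 at 3, 24 and 48 h. Unchanged groups simulated against the same controls gave 0.511, 0.508 and 0.5, and controls split between both comparisons gave -0.022, 0.048 and 0.003. The covariance exceeded the simulated one by 0.00465, 0.00777 and 0.00805, but with split controls it was -0.00132, 0.00281 and -4.46e-05, so a response common to both doses is not shown.

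Whether the response to 50 µM differed between times was tested in a fit of the 45 libraries. From 3 to 48 h it changed for 17 of 18432 genes, upward for 11 and downward for 6. Lss went from a log2 change of 0.03 at 3 h to 0.68 at 48 h (difference 0.65 ± 0.112, adjusted p = 0.00752) and Scd1 from 0.32 to 0.92 (0.60 ± 0.123, adjusted p = 0.0256). Cpm went from 0.20 to 0.64 (0.44 ± 0.087) and Csf1r from 0.01 to -0.67 (a difference of -0.68 ± 0.151, adjusted p = 0.0462). Fgfr3, a growth factor receptor of growth plate chondrocytes, went from 0.02 to 0.49. For Xbp1 the change was 0.32 at 3 h, 0.01 at 24 h and 0.06 at 48 h, but its difference did not pass (adjusted p = 0.308 and 0.186). For Ihh it did not pass either (difference 0.55, adjusted p = 0.26). Between 3 and 24 h and between 24 and 48 h 0 genes passed by edgeR, with 1212 and 640 at an unadjusted p below 0.05 where chance gives 922, and 0 in DESeq2.

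Calls of separate times overlapped. Of the genes higher at 24 h, 16 were also higher at 48 h, where independent lists would share 0.202, out of 16207 genes tested at both. A further 9 were lower at both, where 0.111 would be shared, and these comparisons share no libraries. Both sets included Scd1, Lss, Cldn11 and Cpm as higher and Osr2 as lower. The 62 genes called at 24 h had the same sign at 48 h in 62 cases, and of 166 genes called at 48 h and tested at 24 h 161 had the same sign there. The calls at 48 h were also set against the change of the controls between 3 and 24 h, which uses other libraries. Of the genes lower at 50 µM, 45 had risen in controls and 10 had fallen, where independent lists would share 17.7 and 17.1. Of the genes higher at 50 µM, 48 had risen and 10 had fallen, where 16.4 and 15.9 would be shared.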

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

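In this part, the fits with the Y-linked level as a covariate and the test of a lower share of all non-skeletal cells were chosen only after the result was seen.

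Single libraries stood apart from the other 4 of their group, by a gap to the nearest one above 0.71 of the group's range (Dixon's critical ratio). The ratio was 0.717 for genes detected in 50 µM 24 h replicate 5 (22320 against 24080 to 24780) and 0.716 for the share of globin reads in 50 µM 3 h replicate 1 (0.184% against 0.217% to 0.231%). List scores gave 0.80 for fatty acid synthesis in 10 µM 3 h replicate 1 (5.32 against 5.42 to 5.44 log2 CPM). For hypoxia and glycolysis they gave 0.824 in control 3 h replicate 5 (5.63 against 5.55 to 5.57), 0.748 in 50 µM 3 h replicate 2 (5.73 against 5.36 to 5.45) and 0.906 in 50 µM 48 h replicate 2 (5.96 against 5.40 to 5.45). Chance marks about 1 in 20 groups in this way, and 2 of 45 library measures, 4 of 72 list scores and 15 of 252 gene levels were marked where 2.2, 3.6 and 12.6 would be by chance.

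The 15 gene levels were marked in 3, 24 and 48 h libraries alike. In controls these were Rbm25 in 3 h replicate 3 (ratio 0.893, 211.5 CPM), Aldh1l2 and Aplnr in 24 h replicate 5 (0.76 and 0.763, at 29.2 and 8.27 CPM), Crip2 in 24 h replicate 1 (0.784, 38.3 CPM) and Scd2 in 24 h replicate 2 (0.756, 1251 CPM). At 48 h the control values were C1qa in replicate 1 (0.757, 41.6 CPM against 27.1 to 30.6), Msr1 in replicate 2 (0.738, 2.74 CPM) and Runx2 in replicate 3 (0.775, 79.9 CPM). At 10 µM and 48 h they were Aldh1a3 in replicate 3 (0.823, 19.3 CPM) and Cpm in replicate 4 (0.771, 101.6 CPM). At 50 µM and 24 h they were Dpysl5 in replicate 4 (0.879, 15.4 CPM) and Osr2 in replicate 2 (0.833, 39.9 CPM). At 50 µM and 48 h they were Col2a1 in replicate 3 (0.771, 9322 CPM), Csf1r in replicate 5 (0.765, 21.5 CPM against 14.3 to 16.0) and Mmrn1 in replicate 1 (0.738, 1.05 CPM).

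The response to 50 µM differed between 48 and 3 h for 17 genes in the edgeR interaction test, with adjusted p from 0.00752 to 0.0462. Among them the difference of the log2 changes, 48 h minus 3 h, was 0.77 for Cth, 0.65 for Lss, 0.60 for Scd1, 0.60 for Gm49338, 0.51 for Slc7a1, Gdf10 and Slc25a37, 0.47 for Fgfr3, 0.45 for Nav2, 0.44 for Cpm and 0.41 for Extl1. It was -1.18 for Mmrn1, -0.68 for Pde1b and Csf1r, -0.52 for Haghl and -0.42 for Tmem119. Of 30 assignments of the control and 50 µM labels within times, the real one included, only the real one gave as many genes. The highest of the others gave 1 gene. Mixing the labels also breaks up a dose response common to the times, so this does not test the difference between times by itself.

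The cholesterol list rose at 50 µM and 48 h by a median of 0.44, in libraries whose Y-linked level was also higher (205.9 ± 41.5 against 117 ± 36.3 CPM). The slope on that level within the 9 groups predicts a change of the list score of -0.005 ± 0.017 where 0.425 was seen. This argues against another sex makeup of the pooled limbs. With the Y-linked level as a covariate the median was 0.67. That level hardly overlapped between the groups at 48 h, so the covariate fit cannot decide the question. The tables argue against 1 deviating control library and against a trend with gene length or expression as well. Without control replicate 1 the median was 0.42, and the highest of 10000 random lists matched on length and expression was 0.095. The strain labels of the 50 µM libraries at 48 h, CD2 to CD6, stay open for the 48 h value, while at 24 h, where all labels read CD1, the list score was higher by 0.239 with a Y-linked level of 125.9 ± 73.4 against 165.6 ± 29.2 CPM. A response of this pathway to 50 µM BPS may account for the pattern and stays a hypothesis, since it was found and tested on the same libraries.

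The macrophage list lay below controls at 50 µM and 48 h by a median of -0.40 (adjusted p = 1.77e-16), but was not called with an estimated correlation (adjusted p = 0.0589). It did not decline over time at this dose. Its scores in the 50 µM libraries were 2.73 to 3.00 log2 CPM at 24 h and 3.22 to 3.75 at 48 h. Another sex makeup is argued against by the slope within groups, which predicts a change of 0.008 ± 0.03 where -0.443 was seen. With the Y-linked level as a covariate the median was -0.65, a fit that cannot decide this for the reason given above. A lower share of all non-skeletal cells alike is argued against too, because 3 of 4 other cell type lists stayed above this one, with changes of -0.042 for muscle, 0.053 for epidermis and -0.106 for nerve (two-sided exact permutation p = 0.0159, 0.0317 and 0.00794, the smallest possible, but 0.0952 for endothelium). Adjusted over 5 lists muscle and nerve passed (adjusted p = 0.0398 and 0.0397) and epidermis did not (0.0528). The difference from the erythroid list missed the threshold (exact p = 0.214), and fewer macrophages or a lower level of these genes in each of them cannot be separated in pooled RNA. Fewer macrophages than in controls, or a lower expression in them, at 50 µM BPS may underlie the difference, as a hypothesis. The strain labels stay open here as well.

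At 24 h, exchanging control replicate 5 and 50 µM replicate 1 gave 317 genes, against 62 under the labels, which points to a structure of the samples. The count was also 315 without control replicate 5 and 105 without 50 µM replicate 1. If the labels of these libraries had been swapped, both should lie near the other group on the genes called at 48 h, which use no 24 h library. The shifts towards the other group were 0.118 of the gap for 50 µM replicate 1 and 0.303 for control replicate 5, with a gap of 0.557 log2 units and an SD of 0.161 of it among the other 8 libraries. This argues against a swap, what sets these libraries apart stays open, and no biological explanation was tested.

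Other splits of the same 10 libraries into 2 groups of 5 were fitted for each comparison, 100 of the 126 possible, the real one included. For 50 µM at 48 h 1 split gave at least the real 167 genes, the real one, and the highest of the others was 1. For 50 µM over 10 µM at 48 h 1 split gave at least 152, with 6 as the highest other. In the control comparisons from 3 to 24 h, 24 to 48 h and 3 to 48 h, 1 split each gave the real 6642, 2670 and 8304 genes, with 2, 1 and 0 as the highest others. For 50 µM at 24 h 2 splits gave at least 62 genes. The highest other gave 317, which points to a structure of the samples. In the other comparisons named so far no other fitted split reached the real count, though not all 126 were fitted. For 50 µM at 3 h 4 splits gave at least the real 9 genes, and the highest other gave 795, which points to a structure of the samples. That split set control replicates 3 and 4 and 50 µM replicates 3, 4 and 5 against the rest. Of the 16 splits that, like the real one, part all 5 same-numbered pairs, the highest other gave 1 gene, and with the replicate number as a block 1 against the real 256, but 16 splits are too few for a share under 0.05.

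Where the real split gave 0 genes, all 100 splits reach that count by construction, so they say nothing about chance there. For 10 µM at 3, 24 and 48 h the highest other splits gave 284, 56 and 10 genes, and those at 3 and 24 h again point to a structure of the samples. The one at 24 h set 10 µM replicates 3, 4 and 5 and control replicates 3 and 4 against the rest. The hypoxia and glycolysis scores of the named libraries were 5.07 to 5.20 log2 CPM, and those of the rest 5.63 to 6.45. That match was seen after the split was known, and its cause was not tested. For 50 µM over 10 µM the highest others gave 7 at 3 h and 3 at 24 h. For the interactions between 24 and 3 h and between 48 and 24 h all 30 reassignments likewise reach the real 0 by construction, with 6 and 3 as the highest others.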

How the results depend on the processing

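In this part, the fits with the Y-linked level as a covariate were chosen only after the result was seen. All other alternatives were planned, and the cause of the moves given next was not tested unless stated. The pseudocount alternative for normalised values was not run, since the counts were tested, and leaving out single libraries was not run for the interactions and the dose correlations. Scaling by DESeq2 size factors moved the median of all genes by at most 0.0079 on the log2 scale and gave 2 genes for 50 over 10 µM at 24 h, where the main setting gave 0. It kept every other count of genes within 1.5 times. Over all alternatives the named genes kept their side of the threshold in 10990 cases, lost the call in 918 and gained one in 116. No gene called in either fit reversed its direction. Genes called in neither fit, such as those of 10 µM, count among the 10990, and their direction was not compared. The 918 include calls lost by construction at the limit of 1 on the absolute log2 fold change. On data simulated for 50 µM at 48 h, 72% of genes changed 1.5-fold were recovered.

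A limit of 1 on the absolute log2 fold change left, by its construction, 0, 3 and 7 genes for 50 µM at 3, 24 and 48 h, 950, 393 and 1854 genes for the control comparisons of 24 over 3 h, 48 over 24 h and 48 over 3 h, 19 for 50 over 10 µM at 48 h and 1 for the interaction of 48 and 3 h. Without the filter on low counts the counts for 50 µM were 60 at 3 h, 2.4e+02 at 24 h (153 higher and 90 lower) and 258 at 48 h. For 50 over 10 µM they were then 13, 41 and 469 at the 3 times, and 1 for 10 µM at 3 h. DESeq2 called 59, 266 and 426 genes for 50 µM, 7, 37 and 352 for 50 over 10 µM and 77 for the interaction of 48 and 3 h. Limma-voom called 16, 430 and 516 for 50 µM and 4, 26 and 248 for 50 over 10 µM. The fit of all 45 libraries called 16, 104 and 477 for 50 µM, 1 and 10 for 50 over 10 µM at 3 and 24 h, and 4063 for 48 over 24 h in controls. DESeq2 called all of the main 9, 62 and 167 genes of 50 µM, and the fit of 45 libraries 7, 42 and 158 of them.

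With the replicate number as a block 256 genes passed for 50 µM at 3 h. At other comparisons not every same-numbered pair correlated above 0.1, the limit set here, so the numbers were not taken to pair the libraries. There the block gave 949 genes for 50 µM at 24 h (621 higher and 328 lower, with all 62 among them), 70 for 50 µM at 48 h, 181 and 328 for 50 over 10 µM at 24 and 48 h, 28 for the interaction of 48 and 3 h and 4 lists for 10 µM at 24 h. It changed no other count of genes, or of lists at the preset correlation, by more than 1.5 times. With the block and an estimated correlation the called lists went from 5 to 0, 0 to 1 (cholesterol, adjusted p = 0.0346) and 3 to 0 for 50 µM at 3, 24 and 48 h (at 48 h 0.0728 for cholesterol and fatty acid genes and 0.124 for BMP targets). They went from 11 to 2, 4 to 2 and 11 to 3 for 24 over 3 h, 48 over 24 h and 48 over 3 h in controls, and stayed at 0 for 10 µM. Each library correlated best with its own number in 9 of 10 cases for 50 µM at 24 h (correlations of the pairs 0.079 to 0.246), in 10 of 10 for 50 over 10 µM at 24 h (0.084 to 0.243) and in 6 of 10 for 50 µM at 48 h (-0.067 to 0.122), a hint from the data and not from the design.

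With the Y-linked level as a covariate 23 genes passed for 50 µM at 3 h, including the main 9, and 35 at 48 h, with 25 of the main 167. At 24 h the covariate gave 42 genes, 32 of them among the main 62. At 48 h the Y-linked level of the groups hardly overlapped, so the covariate shares much of its range with the treatment. The hypoxia and glycolysis list then changed direction (adjusted p = 0.00378), as did endothelium (0.609) and erythroid genes (0.599). Called lists of camera with an estimated correlation were 0 for 10 µM at 3 h and at 48 h, 5, 0 and 3 for 50 µM at 3, 24 and 48 h, and 11, 4 and 11 for the control comparisons of 24 over 3 h, 48 over 24 h and 48 over 3 h. The correlation of the changes at both doses, 0.509, 0.554 and 0.48, fell to -0.022, 0.048 and 0.003 with the controls split so that the doses share no library, and the first of these reversed.

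With single libraries left out, the count for 50 µM at 3 h ranged from 1 (without control replicate 2 or 5 or 50 µM replicate 1 or 4) to 18 (without 50 µM replicate 2). At 24 h it ranged from 2 (without 50 µM replicate 4) to 315 (without control replicate 5), and at 48 h from 55 (without 50 µM replicate 4) to 282 (without control replicate 1). For 50 over 10 µM it ranged from 0 to 2 at 3 h (10 µM replicate 3), from 0 to 12 at 24 h (10 µM replicate 3) and from 88 (10 µM replicate 1) to 203 (10 µM replicate 3) at 48 h. At 10 µM it stayed at 0 at each time. Lists called at 10 µM ranged from 3 to 6 at 3 h (10 µM replicate 4), from 0 to 7 at 24 h (control replicate 5) and from 2 (control replicate 5) to 12 (10 µM replicate 5) at 48 h. At 50 µM they ranged from 8 to 13, 9 to 17 and 16 to 21 at the 3 times. Counts of genes in the control comparisons ranged from 5960 to 6844, 1957 to 2891 and 7564 to 8652. At 10 µM and 48 h the hypoxia list changed direction without 10 µM replicate 3 (adjusted p = 0.448) and ranged from 7.33e-08 (10 µM replicate 2) to 0.932 (control replicate 5). The ribosomal list did so without control replicate 1 (adjusted p = 2.85e-05, the lowest), and its highest was 0.452 (10 µM replicate 4).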

Other observations

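In this part, the tests of the hypoxia score by replicate number and of the 48 h genes in the 24 h libraries were chosen only after the result was seen.

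Other gene groups also moved in control culture. Of 24 tested genes of the integrated stress response and amino acid starvation, 17 fell and 1 rose between 3 and 24 h (17 and 1 adjusted over the list alone, median -0.59, adjusted p = 4.3e-15, and adjusted p = 0.0250 with an estimated correlation). Atf3, a stress-induced transcription factor, fell from 27.9 ± 3.73 to 8.39 ± 1.42 CPM and Asns, the asparagine synthetase, from 129.5 ± 8.26 to 70.0 ± 5.73 CPM (n = 5 each, edgeR). Over the same interval 14 of 17 ER chaperone genes rose (15 higher and 1 lower adjusted over the list alone, median 0.33, adjusted p = 8.83e-09, and adjusted p = 0.0220 with an estimated correlation), with Hspa5 at 720.3 ± 37.2 CPM after 509.7 ± 8.65 CPM. From 3 to 48 h neither list passed with an estimated correlation (adjusted p = 0.434 and 0.0805). Nerve and Schwann cell genes fell in 10 of 16 cases and 1 rose (10 and 2 adjusted over the list alone, median -0.52, adjusted p = 0.00103, and adjusted p = 0.0245 with an estimated correlation). Sox10, a transcription factor of Schwann cells, went from 23.5 ± 2.42 to 9.17 ± 0.753 CPM.

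From 3 to 48 h, 11 of 19 genes of the joint interzone, tendon and perichondrium rose and 5 fell (11 and 5 adjusted over the list alone, median 0.40, adjusted p = 1.2e-05, and adjusted p = 0.0302 with an estimated correlation). Tnmd, a membrane protein of tendon, went from 10.3 ± 0.984 to 75.7 ± 12.0 CPM. Inflammatory and matrix proteinase genes rose in 9 of 12 cases and 2 fell (9 and 2 adjusted over the list alone, median 1.17, adjusted p = 0.00016, and adjusted p = 0.0163 with an estimated correlation). Ptgs2, which encodes an inducible cyclooxygenase, rose from 0.251 ± 0.0651 to 3.55 ± 0.824 CPM and Mmp9, a matrix proteinase, from 10.3 ± 0.586 to 35.8 ± 4.85 CPM.

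The labels state that limbs of both sexes were cultured together. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 in control 3 h replicate 1, 10 µM 3 h replicate 2, 50 µM 3 h replicate 2 and 50 µM 24 h replicate 1, where Xist stood at 1601, 1578, 1463 and 2030 CPM. Xist stood at 1.525, 1.112, 1.108 and 0.118 CPM in 10 µM 3 h replicate 1, 10 µM 24 h replicate 1, 10 µM 48 h replicate 4 and 50 µM 48 h replicate 5. In the other libraries reads of both kinds were present.

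Scores of the hypoxia and glycolysis list spread widely within groups, by up to 1.379 log2 units among the 10 µM libraries at 24 h. At 24 h the scores were 6.43 and 6.05 log2 CPM in control replicates 1 and 2 and 6.03 and 6.45 in 10 µM replicates 1 and 2, but 5.24 and 5.76 in 50 µM replicates 1 and 2. Vegfa, a target of hypoxia signalling, ran from 96.3 to 268 CPM among the 10 µM libraries. As a hypothesis, culture conditions shared by libraries of the same number may set this score. At 24 h the means of the numbers varied more than under reordering of the numbers within the 3 groups (exact permutation p = 0.0227 over 14400 reorderings, adjusted p = 0.0454 for 2 tests). At 48 h the p was 0.378 in the same exact test, and there the effect of a shared number cannot be told apart from the spread between libraries.

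Whether genes called at 50 µM shift in the same direction at 10 µM was tested on libraries that did not choose the genes. The score is the mean log2 CPM of the higher genes minus that of the lower ones. Genes called at 48 h gave 1.473 ± 0.095 in controls, 1.555 ± 0.075 at 10 µM and 1.983 ± 0.098 at 50 µM in the 24 h libraries (SD, n = 5), a difference of 0.082 ± 0.054 (SE) between 10 µM and control (two-sided exact permutation p = 0.183). Genes called at 24 h gave 0.437 ± 0.218, 0.637 ± 0.097 and 1.201 ± 0.154 in the 48 h libraries, a difference of 0.20 ± 0.107 with SE (two-sided exact permutation p = 0.0873, adjusted p = 0.175 for 2 tests). By replicate number 1 to 5, the 48 h genes scored 1.386, 1.377, 1.499, 1.497 and 1.608 in the 24 h controls. The 10 µM libraries of 24 h scored 1.49, 1.54, 1.527, 1.535 and 1.685, each above its same-numbered control, and no paired test was run. A smaller response of the same genes at 10 µM may exist, but with 5 libraries per group these unpaired tests cannot tell it apart from no response. The 50 µM libraries differed from controls in both tests (exact permutation p = 0.00794, the smallest possible).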
